A study of Mus musculus with 4 samples.

How the data were processed

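Total RNA was sequenced from mouse embryonic fibroblasts, primary connective tissue cells grown from embryos aged 13.5 days, taken 8 hours after infection with 100 haemagglutination units of Sendai virus, a mouse paramyxovirus with an RNA genome. There were 4 libraries, 2 from cells with intact Dtx2 (wild type) and 2 from cells lacking Dtx2 (knockout), and each library was placed in its group by the labels. No uninfected library was analysed here, so every value is a level in infected cells and no induction by the virus was computed. The labels do not say whether the 2 libraries of a genotype came from separate embryos or cultures, so the p-values measure only the spread between these libraries, which may be technical. Per the labels, wild type replicate 1 was sequenced on lane 3 and the other 3 libraries on lane 4.

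The deposited values were raw read counts per gene, whole numbers that were not normalised, in 24421 rows. Every row carried the same gene symbol in both parts of its name, so 0 rows lacked a gene name, and 0 value columns were left unused. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.6, HISAT2 2.2.1, SAMtools 1.3.1 and DESeq2 were used with the GRCm39 build. The counting program, the gene annotation and the strand setting are not given in the sources used here. Reads of near-identical genes and of overlapping genes could therefore have been split or dropped in ways that cannot be seen in the counts, and such genes are named as uncertain. The reference at hand was GRCm38 with GENCODE vM21 and RefSeq gene tables. It served only for older symbols, chromosome names, the order and strand of neighbouring genes and the length of the longest transcript (found for 24069 rows), and no coordinates are given because its build differs from that of the counts.

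Total counts were 61404077 and 61985204 in wild type replicates 1 and 2, and 62173741 and 59745263 in knockout replicates 1 and 2. A count of 0 in a library was taken to allow up to 3 counts, which is 0.0495 and 0.0508 counts per 1000000 (CPM) in the wild type libraries and 0.0476 and 0.0479 CPM in the knockout libraries. Where a gene had 0 counts in both knockout libraries, its fold change was computed against this floor in each library and is given as a lower bound. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

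Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by the trimmed mean of M values, which gave factors of 0.988 and 0.952 for the wild type and 1.01 and 1.05 for the knockout libraries. Genes passing filterByExpr with its defaults (minimum count 10, minimum total count 15) were kept, which left 14415 genes. CPM values use the scaled library sizes and are given as mean ± SD over 2 libraries. Genotype was tested with the robust quasi-likelihood fit and its two-sided F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. The log2 fold change is knockout minus wild type and has a standard error (SE). The common dispersion was 0.113.

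Before the data were examined, the test, the gene lists and the rule for the genes to be named were fixed. There were 8 main lists: type I and III interferons, interferon-stimulated genes, IRF3-responsive virus-induced genes, NF-kB targets, guanylate-binding and immunity-related GTPases, MHC class I presentation, RNA sensing and TBK1 pathway components, and the Deltex family. Context lists covered the Notch pathway, the cell cycle, p53 targets, matrix and fibroblast genes, contractile genes, the unfolded protein and integrated stress response, the heat shock response, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded genes, ribosomal proteins, histones, Hox genes, Y-linked genes, X inactivation, and markers of macrophages, endothelium, epithelium, neural cells, skeletal muscle, adipocytes, cartilage and bone, and erythroid cells. The mitochondrially encoded list of 13 symbols matched 0 rows and was not analysed here. Each of the 29 lists with at least 3 measured members was tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, with adjustment over the lists. Camera with an estimated correlation and fry were the alternatives.

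The rule for named genes took Dtx2, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 CPM and no overlap between the groups, leaving out predicted genes. It added the 4 members with the smallest p of each main list, the 3 with the smallest p of each context list past camera, and 12 antiviral readouts whatever their p. Fewer than 10 genes rose, so all 5 were named. The rule gave 63 genes, and any other gene named was chosen after its values were seen.

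The scripts were tested on simulated counts with the means and library sizes of these libraries, 14107 genes after filtering and 200 genes changed. At 2 against 2 libraries, edgeR recovered 6% of 2-fold, 62% of 4-fold, 94% of 8-fold and 100% of 32-fold changes, with 13 false calls. DESeq2 recovered 28%, 88%, 98% and 100% of them with 52 false calls. A simulated list of 30 genes, each lowered 2-fold, was tested among 14126 genes. It was found by camera with the preset correlation (adjusted p = 2.7e-25) and by fry (adjusted p = 0.020). Camera with an estimated correlation missed it (adjusted p = 0.27). Of 40 unmoved lists, the preset correlation called 1, and the estimated correlation and fry called 0. The simulated genes varied independently, so lists whose genes vary together were not tested in this way.

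The alternatives were DESeq2 size factors, library size alone, no filter beyond 1 read, a stricter filter (1 CPM in 2 libraries and a mean of 2 CPM), the DESeq2 1.42.0 test, limma-voom, the replicate number as a block, each library left out in turn, a threshold of 0.01 and a 2-fold minimum. After the data were seen, removal of a smooth length trend from each library (lowess, span 0.3), a block with crossed numbers, and a fit without X and Y chromosome genes were added. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.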

Results

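RNA levels were compared between wild type and Dtx2 knockout mouse embryonic fibroblasts, all infected with Sendai virus for 8 hours, with 2 libraries per genotype. Dtx2 encodes an E3 ubiquitin ligase of the Deltex family, and the series addresses its part in the antiviral response that runs through the kinase TBK1. Depth was even, with 59745263 to 62173741 counts per library and 15849 to 16076 genes detected.

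Dtx2 itself was lower in both knockout libraries. It was at 23.9 ± 0.116 CPM in the wild type and 5.47 ± 0.260 CPM in the knockout libraries (SD, n = 2 each), which is 4.37-fold lower (log2 fold change -2.13, SE 0.28, adjusted p = 0.0332, edgeR). The knockout libraries kept 333 and 354 counts of Dtx2, against 1454 and 1405 in the wild type. The part of the gene that was altered is not given in the sources used here, and the remaining counts were not placed along the gene. The fold change moved little when a knockout library was left out, but the call ended, with an adjusted p of 0.169 without knockout replicate 1 and 0.116 without knockout replicate 2.

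The 4 libraries also differed by embryo sex and in 1 case by transcript length. Xist, the RNA that coats the inactive X chromosome of female cells, had 0 and 0.475 CPM in the wild type and 557 and 451 CPM in the knockout libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 8.97 to 98.4 CPM in the wild type libraries and had 0 counts in both knockout libraries. The wild type libraries thus carried male and the knockout libraries female transcripts, and sex and genotype could not be separated in any comparison that follows. Across genes, Spearman's rho was 0.961 between the wild type libraries and 0.987 between the knockout libraries. Both pairs differed by more than counting noise, with a chi-square per degree of freedom of 462 and 104. Wild type replicate 2 stood apart from the other 3 by transcript length: its median log2 deviation from the mean of the 4 libraries ran from 0.49 in the tenth of genes with the shortest transcripts (median 1115 nt) to -0.50 in the tenth with the longest (median 8366 nt).

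**Figure D1:**
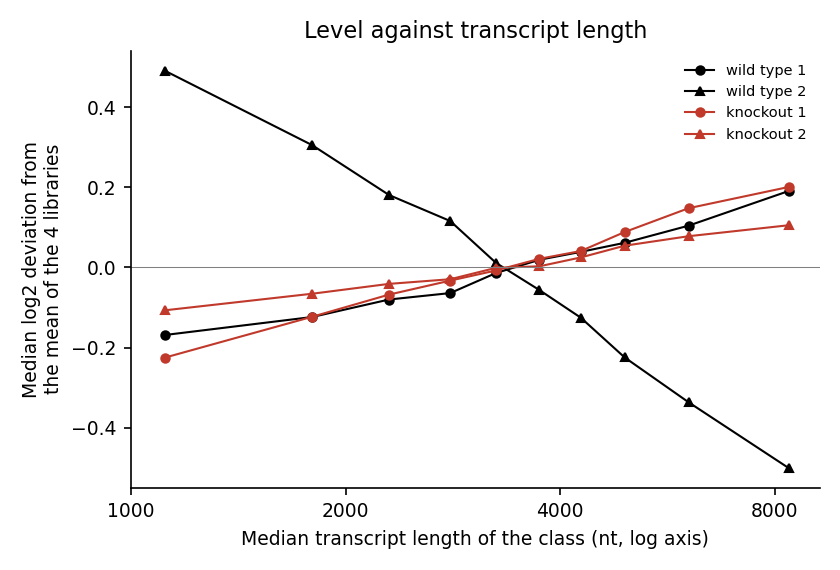
Median log2 deviation of each library from the mean of the 4 libraries (vertical axis) in 10 classes of genes by transcript length in nucleotides (horizontal log axis). Wild type replicate 2 falls from 0.49 to -0.50 and the other 3 libraries rise by less.

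Between genotypes, antiviral and inflammatory genes were lower in the knockout libraries. Of 14415 genes tested, 147 were lower and 5 were higher in knockout (edgeR, adjusted p under 0.05), and 723 were lower and 437 higher at an unadjusted p under 0.05. The fall was large: 141 of the 147 genes were at least 4-fold and 62 at least 32-fold lower, with a median log2 fold change of -4.39 against -0.004 over all genes tested. An antiviral or immune main list held 85 of the 147 genes, and 4 were Y-linked. Some of the lower genes had 0 counts in both knockout libraries, so that their falls are given as bounds. Il1b and Il12b, which encode inflammatory cytokines, were at least 1421-fold and at least 940-fold lower. Cd69, a marker of activated leukocytes, was at least 454-fold lower, the growth factor gene Csf2 at least 134-fold and the chemokine gene Cxcl11 at least 129-fold. These bounds rest on wild type libraries that differed: replicates 1 and 2 were at 40.9 and 94.7 CPM for Il1b, 2.52 and 10.3 CPM for Csf2 and 9.48 and 2.80 CPM for Cxcl11. Against the lower of the 2 the bounds are 857-fold, 52.9-fold and 58.6-fold. Irg1, which encodes the enzyme that makes itaconate, went from 125 ± 44.9 to 0.0796 ± 0.0228 CPM (SD, n = 2 each), which is 1569-fold lower (adjusted p = 0.00696, edgeR).

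**Figure D2:**
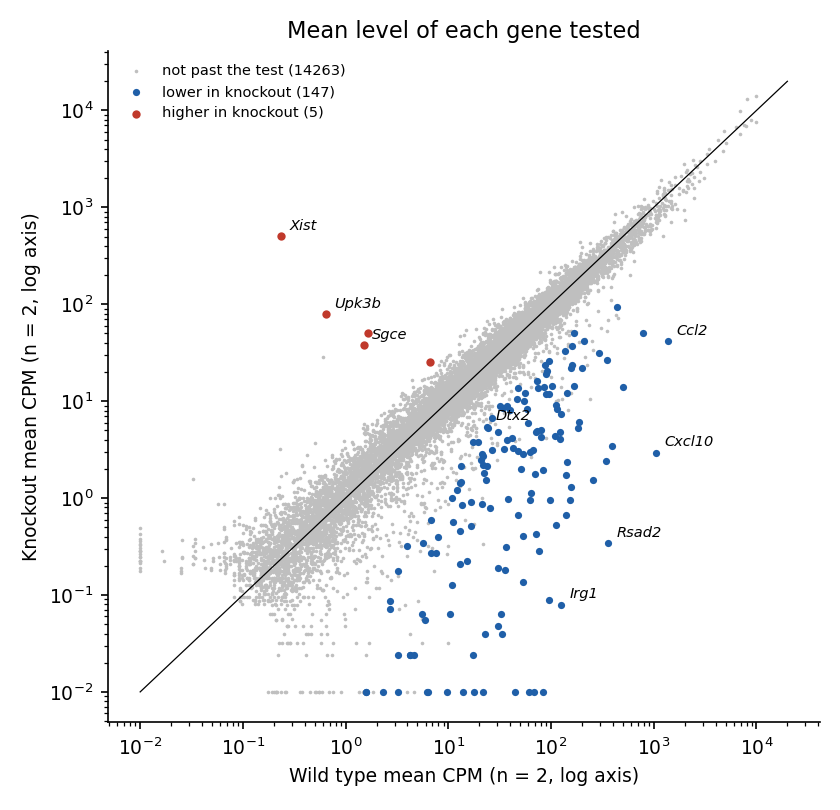
Mean CPM of each gene tested in the wild type (horizontal log axis) and the knockout libraries (vertical log axis), n = 2 each, with means under 0.01 CPM drawn at 0.01 CPM. The 147 genes lower in knockout (blue) lie below the line of equal levels, the 5 higher genes (red) above it.

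These counts depended on which wild type library was used. Without wild type replicate 2, 315 genes were lower and 23 higher, and without wild type replicate 1, which leaves only libraries from lane 4, 212 were lower and 159 higher. The first set held 142 and the second 135 of the 147 lower genes, and all 147 stayed below 0 in both. Lane 3 held a wild type library alone and gives no comparison of its own. DESeq2 called 409 genes lower, all 147 among them, and 60 higher. With the length trend removed from each library, a correction chosen after the trend was seen, the calls of Ccl5, Csf2, Cxcl11, Xist and Adra1d ended (adjusted p = 0.0893, 0.0507, 0.0609, 0.0609 and 0.0623, edgeR). As fitted, their log2 fold changes and SE went from -6.02 ± 0.71 to -5.84 ± 0.96, from -11.61 ± 1.48 to -11.31 ± 1.19, from -11.56 ± 1.36 to -11.60 ± 1.33, from 11.05 ± 1.27 to 10.29 ± 1.45 and from 1.94 ± 0.29 to 1.98 ± 0.28. The SE grew for Ccl5 and Xist; for Cxcl11 and Adra1d fold and SE moved little and the unadjusted p rose from 0.000287 to 0.000613 and from 0.000412 to 0.000649; for Csf2 the unadjusted p stayed at 0.000422 and 0.000425, and the call ended through the adjustment. Limma-voom ended those of Csf2, Cxcl11, H2-T10 and Kdm5d (adjusted p = 0.0982, 0.0704, 0.0525 and 0.0510).

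Interferon-stimulated genes fell as a group. All 83 measured members had negative fold changes, with a median log2 fold change of -3.23; 38 passed the test over all genes tested and 79 passed adjusted over the list alone. Rsad2, which encodes the antiviral enzyme viperin, went from 362 ± 214 to 0.342 ± 0.190 CPM (adjusted p = 0.00995, edgeR), and Ifit1, which encodes a protein that binds viral RNA, from 394 ± 167 to 3.46 ± 1.86 CPM (114-fold lower, adjusted p = 0.0105; SD, n = 2), with log2 fold changes from -10.78 to -9.26 and from -7.55 to -6.32 when 1 library was left out. Ifit3 was 143-fold and its near-identical neighbour Ifit3b 121-fold lower (log2 fold changes from -7.65 to -6.40 and from -7.45 to -6.08 with 1 library left out), and reads shared between the pair make the split uncertain. Tor3a was 11.6-fold lower. Isg15, a ubiquitin-like modifier, and Ifit2 did not pass over all genes: Isg15 was at 146 ± 27.1 and 8.05 ± 7.28 CPM (adjusted p = 0.0758), Ifit2 at 124 ± 84.4 and 14.1 ± 0.142 CPM (adjusted p = 0.0656). Camera placed the list lower (adjusted p = 6.95e-157). With an estimated correlation, a setting that missed the simulated list, camera gave an adjusted p of 0.142. Fry, which found the simulated list, gave an adjusted p of 0.0935, so the call ended under both alternatives. Fry also ended each of the other list calls that follow. The camera calls thus rest on the preset correlation of 0.01 between genes.

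Genes that respond to the transcription factor IRF3, which TBK1 phosphorylates, were lower by a median log2 fold change of -6.02. Of 19 measured, 13 passed over all genes and 18 adjusted over the list alone, all lower. Only 9 of the 19 are held by no other main list, so the fall is not separate from that of the other lists. Cxcl10, a T cell chemokine, went from 1045 ± 3.15 to 2.95 ± 1.96 CPM (354-fold lower, adjusted p = 0.00995, edgeR), and Ccl5 was 65.0-fold lower (adjusted p = 0.0231). With 1 library left out, the log2 fold changes ran from -9.41 to -7.91 for Cxcl10 and from -6.87 to -5.17 for Ccl5. The list was lower by camera (adjusted p = 2.53e-92), with adjusted p = 0.142 with an estimated correlation. Type I and III interferon genes were hardly detected, and 0 of the 19 in the table passed the low-count filter. Ifnb1, the interferon beta gene, had 50 and 10 counts in the wild type and 0 in both knockout libraries, at least 10.4-fold lower, and at least 3.55-fold without wild type replicate 1. Tested with no filter, its adjusted p was 0.308. Ifna4 had 0 counts in every library.

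**Figure D3:**
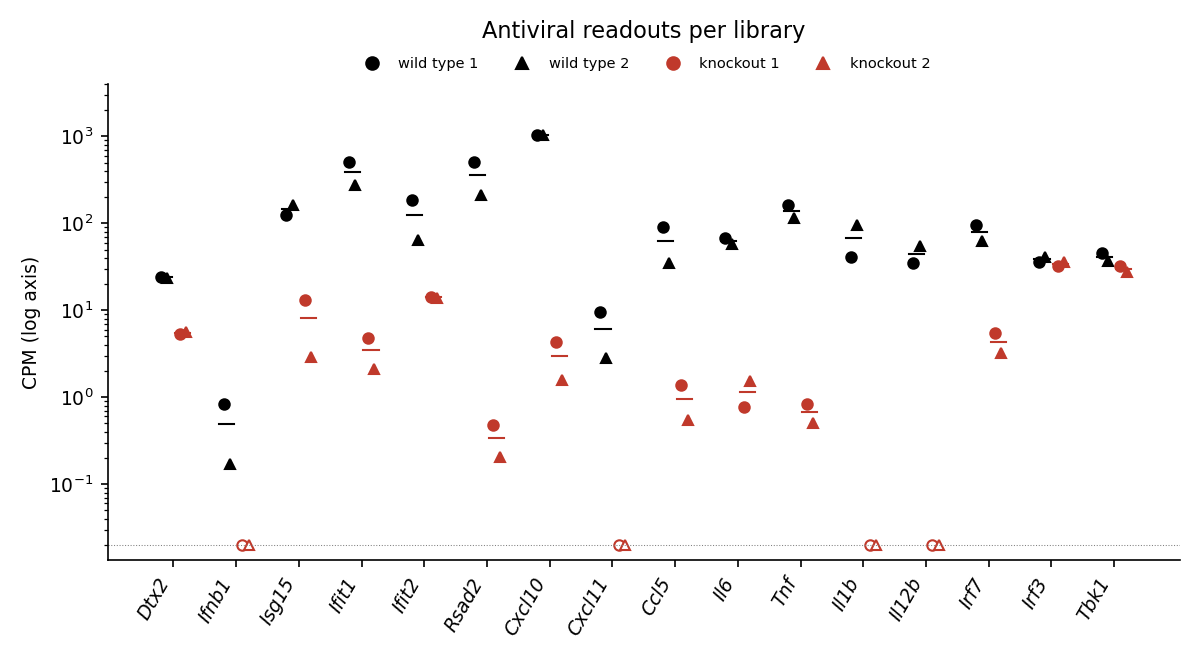
CPM of Dtx2 and 15 antiviral or pathway genes in each library (vertical log axis), with lines at the mean of 2 libraries and open symbols at 0.02 CPM for libraries with 0 counts. Cxcl10 lies at 1045 CPM on average in the wild type and 2.95 CPM in the knockout libraries, and Tbk1 and Irf3 lie close together in both.

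NF-kB target cytokines, chemokines and regulators were lower too. All 48 members were measured and lay below 0, with 27 past the test over all genes, 45 adjusted over the list alone and a median log2 fold change of -3.18. Tnf, the tumour necrosis factor gene, went from 138 ± 33.2 to 0.676 ± 0.233 CPM (205-fold lower, adjusted p = 0.00696, edgeR). Il6 was 55.4-fold lower (adjusted p = 0.00995). The neutrophil chemokine gene Cxcl1 was 168-fold, the macrophage chemokine gene Ccl3 212-fold and the monocyte chemokine gene Ccl2 33.6-fold lower. With 1 library left out, the log2 fold changes ran from -6.37 to -5.41 for Il6, from -7.81 to -7.09 for Cxcl1, from -8.64 to -7.18 for Ccl3 and from -5.26 to -4.86 for Ccl2. Camera gave an adjusted p of 2.15e-139 for the list, and adjusted p = 0.142 with an estimated correlation.

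The interferon-inducible GTPases, which act on the membranes of intracellular pathogens, had a median log2 fold change of -5.46. Of 18 measured, 11 passed over all genes and 18 adjusted over the list alone. Igtp was 42.2-fold and Iigp1 169-fold lower; Tgtp1 and Tgtp2 were 118-fold and 158-fold lower, but these copies share sequence and their split is uncertain. The log2 fold changes ran from -6.03 to -4.97 for Igtp, from -8.43 to -6.65 for Iigp1, from -7.41 to -6.05 for Tgtp1 and from -7.75 to -6.62 for Tgtp2 when 1 library was left out. In MHC class I presentation, 4 of 21 measured members passed over all genes, all lower, and 17 adjusted over the list alone, with a median of -1.76. They were H2-Q4 (13.1-fold), Tap1, which encodes a peptide transporter (10.0-fold), H2-T10 (12.5-fold) and the immunoproteasome gene Psmb10 (4.07-fold). H2 genes are a family of close copies. With the replicate number as a block, the call of H2-T10 ended (adjusted p = 0.0530, edgeR). The H2-T10 call ended without knockout replicate 1 (adjusted p = 0.0775), and the Psmb10 call ended when either knockout library was left out (adjusted p = 0.197 and 0.118). Camera placed both lists lower (adjusted p = 7.34e-71 and 1.46e-29), each with adjusted p = 0.142 with an estimated correlation.

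**Figure D4:**
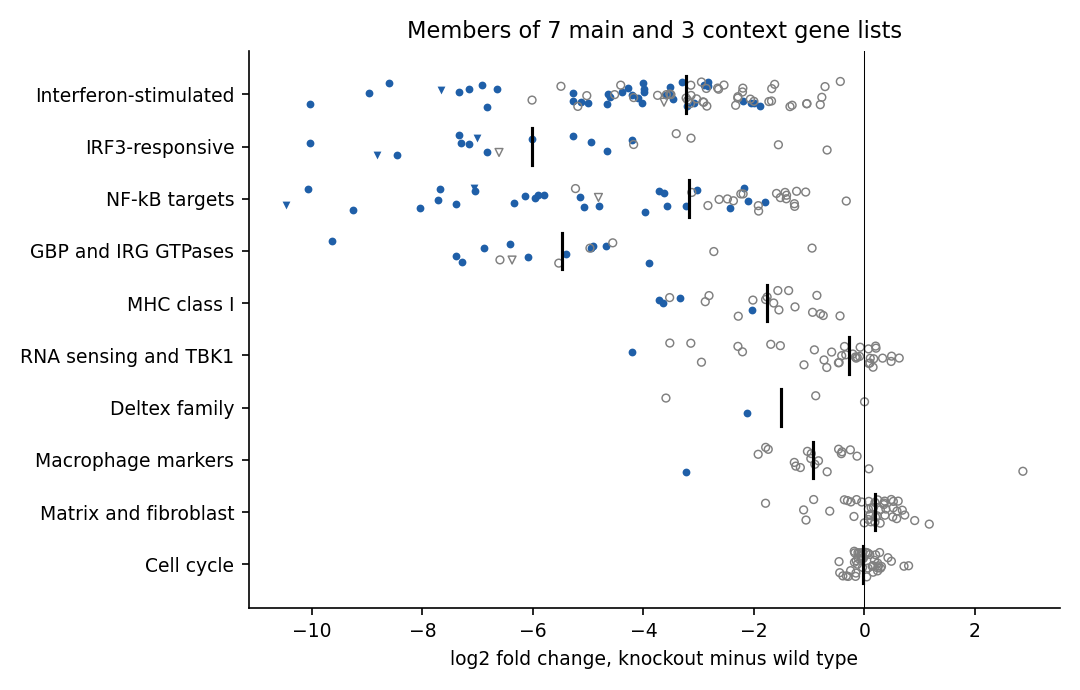
Log2 fold change, knockout minus wild type, of the measured members of 7 main and 3 context lists (horizontal axis). Filled points passed the test, open points did not, triangles are genes with 0 counts in both knockout libraries drawn at their lower bound, and bars mark medians, which lie at -3.23 for interferon-stimulated genes and at 0.19 for matrix and fibroblast genes.

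Of 36 measured components of the sensing pathway, only Irf7, a transcription factor gene that interferon induces, passed over all genes, from 79.6 ± 24.2 to 4.31 ± 1.58 CPM (18.5-fold lower, adjusted p = 0.0144, edgeR). Tbk1 was at 40.9 ± 5.94 and 29.9 ± 3.36 CPM (log2 fold change -0.46, SE 0.26, adjusted p = 0.778) and Irf3 at 38.4 ± 3.21 and 34.3 ± 2.59 CPM (-0.16, SE 0.25, adjusted p = 0.896). Adjusted over the list alone, 8 were lower, among them Trim25, Ifih1 and Dhx58, whose adjusted p over all genes was 0.0542, 0.0633 and 0.0726. Camera placed the list lower (adjusted p = 1.97e-06), with adjusted p = 0.495 with an estimated correlation, and the call ended when members that other main lists hold were left out (adjusted p = 0.225). In the Deltex family, which holds the altered gene, Dtx2 alone passed of 4 measured genes, and 2 adjusted over the list alone. Dtx3l, an interferon-inducible member, was at 127 ± 87.5 and 10.5 ± 4.33 CPM (adjusted p = 0.0665), Dtx4 at 28.4 and 15.4 CPM (adjusted p = 0.632) and Dtx3 at 28.5 and 28.6 CPM (adjusted p = 0.997). The family's camera call (lower, adjusted p = 3.13e-05) had adjusted p = 0.193 with an estimated correlation, and rests in part on Dtx2 itself; for the other 3 members it was 0.0116.

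The 5 genes higher in knockout included a pair of neighbours and a neighbour of Dtx2. Upk3b, a uroplakin gene and the next protein-coding gene after Dtx2 on the same strand of chromosome 5, went from 0.648 ± 0.450 to 79.8 ± 8.11 CPM (123-fold higher, adjusted p = 0.0101, edgeR; SD, n = 2). With 1 library left out, its fold ran from 82.6 to 242. Peg10 and Sgce, adjacent imprinted genes on chromosome 6 that are expressed from the paternal copy, went from 1.66 ± 0.748 to 51.0 ± 0.230 CPM and from 1.51 ± 0.360 to 37.9 ± 1.65 CPM (30.6-fold and 25.1-fold higher, adjusted p = 0.0105 and 0.00995). Adra1d, which encodes an adrenergic receptor, was 3.83-fold higher (adjusted p = 0.0439), and Xist was the last of the 5 (log2 fold change 11.05, SE 1.27, adjusted p = 0.0222). With the replicate number as a block, the calls of Adra1d and Xist ended (adjusted p = 0.0658 and 0.0531, edgeR). The fitted Xist value ran from 10.05 to 17.93 with 1 library left out, since wild type replicate 1 had 0 counts and replicate 2 had 28. The calls of Adra1d and Xist ended when either knockout library was left out, with adjusted p = 0.142 and 0.119 for Adra1d and 0.958 and 1.00 for Xist.

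**Figure D5:**
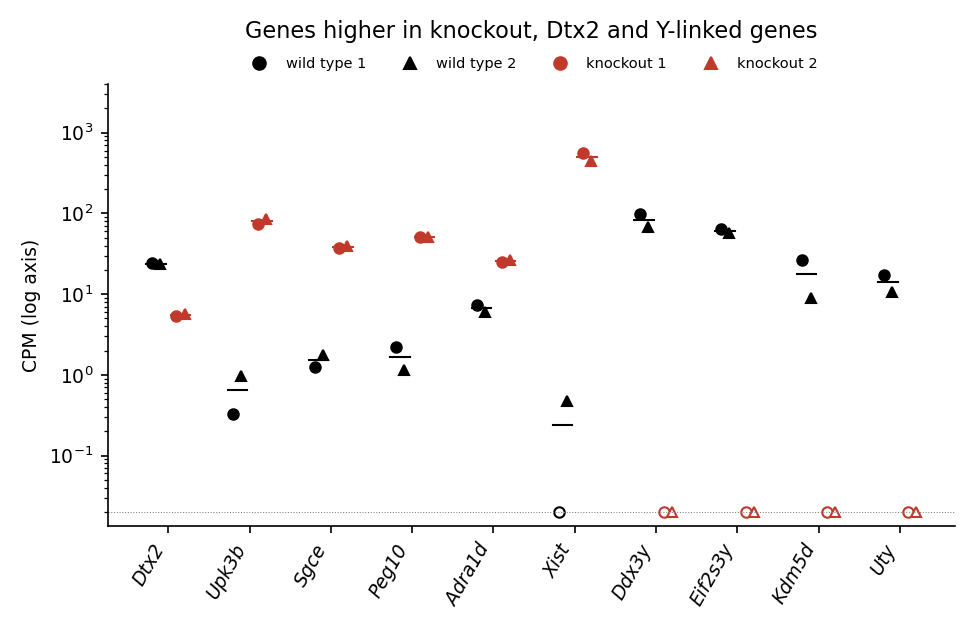
CPM of Dtx2, the 5 genes higher in knockout and 4 Y-linked genes in each library (vertical log axis), with lines at the mean of 2 libraries and open symbols at 0.02 CPM for libraries with 0 counts. Upk3b averages 0.648 CPM in the wild type and 79.8 CPM in the knockout libraries, and the Y-linked genes have 0 counts in both knockout libraries.

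Among the context lists, macrophage markers moved with the antiviral genes, at a smaller size. Of 20 measured, 18 lay below 0, with a median log2 fold change of -0.93 and a camera call of lower (adjusted p = 2.14e-07; adjusted p = 0.364 with an estimated correlation). Cd14, a lipopolysaccharide co-receptor gene, was the only member to pass over all genes (36.8 ± 1.55 to 3.95 ± 0.940 CPM, 9.33-fold lower, adjusted p = 0.0142, edgeR), and adjusted over the list alone 6 were lower and 1 higher. Fcer1g was at 21.7 and 6.29 CPM (adjusted p = 0.0540) and Cx3cr1 at 0.508 and 3.73 CPM (adjusted p = 0.0858). Y-linked genes, 4 of 4 measured, were lower (camera adjusted p = 1.33e-66; adjusted p = 0.142 with an estimated correlation), with a median log2 fold change of -13.98 as fitted and -9.43 with each gene at its bound. In the X inactivation list, Xist alone passed of 3 measured (camera higher, adjusted p = 0.0125; adjusted p = 0.364 with an estimated correlation), while Ftx and Jpx had adjusted p of 0.835 and 0.958. That list's call ended without knockout replicate 1 (adjusted p = 0.249) or 2 (0.0780).

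In 3 further context lists camera passed and no member did by edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 0 ribosomal protein, 7 Hox and 2 cholesterol genes, and DESeq2 called 0, 3 and 0. Of 57 ribosomal protein genes, 56 lay below 0 (median -0.56, adjusted p = 1.06e-05; adjusted p = 0.846 with an estimated correlation), with Rpl3, Rpl38 and Rps14 at log2 fold changes of -0.57, -0.77 and -0.74. Without wild type replicate 2 the direction turned (adjusted p = 0.882), and with the length trend removed from each library the call held (adjusted p = 0.0375). Of 37 Hox genes, which pattern the body axis, 24 lay above 0 (median 0.30, adjusted p = 0.0256; adjusted p = 0.514 with an estimated correlation). Hoxa10, Hoxa3 and Hoxa5 had log2 fold changes of 1.20, 1.45 and 1.36, with adjusted p of 0.195, 0.249 and 0.298. The Hox call ended without wild type replicate 1 (adjusted p = 0.112) or knockout replicate 1 (0.120). Cholesterol synthesis genes had a median of 0.30 (25 measured, adjusted p = 0.0457; adjusted p = 0.889 with an estimated correlation), with Stard4, Hsd17b7 and Dhcr7 at 1.17, 0.76 and 0.86. That call turned direction without wild type replicate 1 (adjusted p = 0.220) and ended without knockout replicate 1 (0.944).

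The remaining 16 context lists tested did not pass camera. The adjusted p was 0.210 for the Notch pathway, 0.639 for the cell cycle, 0.693 for p53 targets, 0.244 for matrix and fibroblast genes, 0.715 for contractile genes, 0.161 for the unfolded protein and integrated stress response, 0.639 for heat shock, 0.199 for immediate early genes, 0.639 for glycolysis and hypoxia and 0.639 for histones. Among markers of other cells it was 0.670 for endothelium, 0.956 for epithelium, 0.441 for neural cells, 0.693 for skeletal muscle, 0.942 for adipocytes and 0.405 for cartilage and bone. The erythroid list had 1 measured member and was not tested. Camera's direction was higher for the cell cycle, contractile and epithelial lists while their medians were -0.02, -0.11 and -0.04. In these 16 lists 1 member passed over all genes, the death receptor gene Fas among the p53 targets (adjusted p = 0.0443, edgeR), which was lower and is named after its value was seen.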

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

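The length trend, the crossed numbers and the fit without X and Y genes were tests chosen after the data were seen; the other settings were planned. Each of the 147 lower genes stayed below 0 in every setting that tested it. Lower genes numbered 147 with DESeq2 size factors, 128 with library size alone, 171 with no filter, 166 with the stricter filter, 123 with limma-voom, 111 with the length trend removed (102 shared with the 147) and 142 without X and Y genes, with 4 or 5 higher genes in each. A 2-fold minimum removed none. DESeq2 gave 409 lower and 60 higher genes, and a threshold of 0.01 gave 18 and 1, fewer by construction. Leaving out 1 library gave 176 to 315 lower and 5 to 159 higher genes; the lone library is then assumed to vary like the other group. The replicate number as a block gave 172 lower and 3 higher genes and changed the call of no list; same-numbered deviations had a Pearson correlation of -0.30 across genes, so the numbers are not taken to pair the libraries. Crossed numbers as a block gave 450 lower and 160 higher genes. Every row has a gene name, so the planned restriction to named rows was not run.

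Dtx2 ranged from -2.17 to -2.11 (log2) with 1 library left out and was not past the threshold when either knockout library was left out (adjusted p = 0.169 and 0.116), with fewer samples. Named genes lost 5 calls with the length trend removed, 4 with limma-voom, 3 with the block, and 5 and 4 without knockout replicates 1 and 2; no named gene past the test turned direction, while Dtx3 and Jpx, not past it, ranged from -0.14 to 0.16 and from -0.88 to 0.85 with 1 library left out.

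For the lists, camera kept every call with DESeq2 size factors, library size alone, no filter and limma-voom. Camera with an estimated correlation missed the simulated lowered list (adjusted p = 0.27), while fry found it (adjusted p = 0.020). That list was lowered 2-fold and its genes varied independently. The miss therefore cannot tell how this setting treats larger falls of genes that vary together. A call that ends under it shows neither that the list moved nor that it did not. With an estimated correlation 13 of 13 calls ended: adjusted p = 0.142 for interferon-stimulated, IRF3-responsive, NF-kB, GTPase, MHC class I and Y-linked genes, 0.193 for the Deltex family, 0.364 for X inactivation and macrophage markers, 0.495 for RNA sensing, 0.514 for Hox, 0.846 for ribosomal protein and 0.889 for cholesterol genes. With fry the same 13 ended: 0.0935 for interferon-stimulated, IRF3-responsive, NF-kB, MHC class I, Deltex, Y-linked and X inactivation genes, 0.103 for GTPases and macrophage markers, 0.172 for Hox, 0.272 for RNA sensing, 0.641 for ribosomal protein and 0.813 for cholesterol genes. RNA sensing without shared members gave 0.225. The stricter filter gave 0.0663 for Hox genes; the length correction gave 0.0466 for the unfolded protein response and 0.0533 for X inactivation. Leaving out 1 library gave adjusted p ranges of 0.00286 to 0.120 for Hox, 0.0205 to 0.734 for Notch, 0.00384 to 0.249 for X inactivation, 0.0260 to 0.429 for cell cycle, 2.63e-10 to 0.944 for cholesterol, 0.0482 to 0.647 for matrix, 0.0122 to 0.909 for glycolysis, 0.0381 to 0.711 for heat shock, 0.00544 to 0.755 for immediate early, 2.92e-25 to 0.882 for ribosomal protein, 0.0474 to 0.866 for contractile and 3.59e-12 to 0.347 for unfolded protein response genes. Cholesterol genes reversed without wild type replicate 1 (0.220) and ribosomal protein genes without wild type replicate 2 (0.882). The cause was not tested for any of these. Depth limits genes near the floor, such as Ifnb1.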

Other observations

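Apart from the macrophage marker list, which was fixed beforehand, the genes, groups and tests in this part were chosen after the values were seen. Among 22 measured genes for pattern recognition receptors and inflammasome parts, 8 were lower in knockout by edgeR. Clec4e, a receptor gene for glycolipids and dying cells, was 196-fold lower (108 to 283 with 1 library left out), Nlrp3, an inflammasome sensor gene, 32.1-fold (20.6 to 52.0), the peptidoglycan sensor gene Nod2 30.8-fold (21.7 to 42.2) and the lipoprotein receptor gene Tlr2 18.7-fold (9.62 to 27.8), while Fpr2, a formyl peptide receptor gene, had 0 counts in both knockout libraries (at least 32.9-fold lower). Casp4, the lipopolysaccharide-binding caspase gene, was 10.0-fold lower. Tlr4 was at 4.19 and 5.64 CPM (adjusted p = 0.847), and Casp12 at 18.8 and 15.3 CPM (adjusted p = 0.828). Bcl2a1a, Bcl2a1b and Bcl2a1d, survival genes that are near-identical copies, were 135-, 18.3- and 107-fold lower, with an uncertain split between them. Bcl2a1a rests on 0 and 3 knockout counts (95% counting interval of the ratio 45.8 to 657), and Bcl2a1b ran from 12.5- to 34.7-fold with 1 library left out. Bcl2a1d was at 0.0476 and 0.0638 CPM in the knockout libraries, at or near the floor of 3 counts, so its fold is imprecise too. Ch25h, which encodes the enzyme that makes 25-hydroxycholesterol, was 13.6-fold lower.

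Oaz1, the antizyme gene that limits polyamine synthesis, was called lower (211 to 41.3 CPM, adjusted p = 0.0359, edgeR). Its processed copy Oaz1-ps was at 78.2 and 215 CPM (adjusted p = 0.196, edgeR), and the sum of both was at 289 and 256 CPM. The split of reads between these copies is uncertain, and so is the fall of Oaz1. The X-linked genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape X inactivation, had log2 fold changes of 1.10, 0.80, 0.56 and 0.32, with 0 past the edgeR test, 2 at an unadjusted p under 0.05 and 0 by DESeq2.

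The first pattern is the fall of antiviral and inflammatory genes. If the lowered transcripts were made in macrophages, a smaller share of these cells in the knockout cultures would lower constitutive macrophage genes as far. The values argue against that as the whole cause. The 20 markers had a median log2 fold change of -0.93 and a lower quartile of -1.25. The lists fixed beforehand had medians of -3.23 for interferon-stimulated genes and -3.18 for NF-kB targets. The 147 lower genes, at -4.39, were picked by the test and are no fair measure here. In wild type and knockout, Lyz2 was at 153 and 78.8 CPM, Lcp1 at 48.3 and 20.1 CPM and Csf1r at 14.7 and 15.6 CPM. Ptprc was 3.79-fold (2.49 to 5.57 with 1 library left out) and Spi1 3.34-fold lower, not past the test. A smaller share as part of the cause therefore stays open. The comparison covers only transcripts made in macrophages and cannot decide on those made in other cells of the cultures. The sex of the embryos cannot be told apart from genotype, because 0 libraries carried the sex markers of the other genotype, and less virus in the knockout cultures could not be examined, because 0 rows held viral counts. The loss of Dtx2, the difference the design names, stays among the open explanations, untested against these.

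The second pattern is the rise of Upk3b beside Dtx2. Mesothelial cells, which express Upk3b, in the knockout cultures would bring their other transcripts, yet 10 mesothelial markers had a median log2 fold change of 0.29 and an upper quartile of 0.88, against 6.94 for Upk3b, with Krt19 at 28.3 and 27.0 CPM. Msln varied within genotype (9.56 and 2.46 CPM in the wild type, 2.17 and 11.3 CPM in the knockout libraries). Lrrn4 (0.218 and 1.07 CPM), Gpm6a (0.0678 and 0.397 CPM) and Krt7 (3.08 and 5.91 CPM) were higher on average, not past the test. With 1 library left out, folds were 2.78 to 7.07 for Lrrn4 and 0.736 to 3.10 for Krt7. For Gpm6a they were 2.93 to 8.19, with none without wild type replicate 2, since wild type replicate 1 had 0 counts. Run-on transcription from the Dtx2 promoter at its wild type rate would leave Upk3b no higher than Dtx2 had been, given equally stable RNAs. Per kilobase of the longest transcript, Upk3b in the knockout was a median of 5.13 times Dtx2 in the wild type (4.74 to 5.52 over the pairs of libraries). This ratio cannot decide whether transcription ran on, since RNA stability was not measured. A local effect of the altered Dtx2 allele, or of the flanking sequence inherited with it, stays open: of the other 43 neighbours tested, within 30 protein-coding genes on each side, 0 passed the edgeR test (3 at an unadjusted p under 0.05 and 0 by DESeq2), but the share of all genes that passed gives 0.45 among 43, too few to decide.

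The third pattern is the near-absence of Sgce and Peg10 in the wild type libraries. A change over other imprinted genes as well is argued against by 20 measured genes, chosen as paternally expressed. Their median log2 fold change was 0.19 with an upper quartile of 0.67. Zim1 was among the 20, though in mouse it is expressed from the maternal copy. It had the highest log2 fold change of them (1.92), so leaving it out could not raise these values. Zim1, Peg3 and Igf2 were 3.79-, 3.41- and 1.85-fold higher and not past the test (adjusted p = 0.381, 0.489 and 0.445, edgeR). With 1 library left out, the folds ran from 2.71 to 6.30 for Zim1 and from 2.16 to 7.99 for Peg3. Loss of both copies of a wider stretch of chromosome 6 in the wild type cultures is argued against by the tested neighbours. The 19 of them within 15 protein-coding genes on each side had a median of 0.041 and an upper quartile of 0.26. Casd1, next to Sgce, was at 16.5 and 20.6 CPM. Loss of the paternal copy alone would leave neighbours expressed from both copies with the maternal one. Their log2 fold change would then be about 1, if copy number sets their level. The neighbours argue against such a loss over the wider stretch, since 9 of the 19 lay below 0 and the highest was 0.73. Loss of the paternal copy of this gene pair alone stays open, and the values cannot decide it. A difference between the embryos in the imprint of this gene pair may remain, as may an effect of genotype, and neither was tested.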
